A study of Homo sapiens with 16 samples.

How the data were processed

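Gene expression was measured in U937 cells, a human monocytic leukaemia line, that carried AML1-ETO under a tetracycline-controlled promoter. AML1-ETO is the fusion protein of the t(8;21) translocation and joins the DNA-binding part of RUNX1 (AML1) to most of RUNX1T1 (ETO). Total RNA was extracted with TRIzol and hybridised to Affymetrix U95Av2 oligonucleotide arrays, per the labels. The 16 arrays form 8 groups of 2 replicates each. Controls were taken at 0, 24, 48 and 72 h, and induced cells at 12, 24, 48 and 72 h. The labels also speak of controls at 12 h, which were not analysed here.

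The deposited values are linear array intensity values, 1 per probe set and array, for 12626 probe sets. Per the labels, each array has a scale factor, which is 1 for replicate 2 of the induced cells at 48 h. All 16 arrays had the same mean intensity of 1370.9. Divided by the scale factor, 100% of the values were multiples of 0.1 within 0.01 of a step, among the 87.1% of values under 3000 in size. The summary software is not given in the sources used here. Of all values, 25.8% were below 0, as an average difference of perfect match and mismatch probes can be.

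Values under a floor were set to it before log2 was taken. The design fixed before the data were examined named the 20th percentile of all values as the floor, with the 10th as an alternative. These percentiles were -52.65 and -210.7 and have no logarithm. The 40th percentile (135.61), which that design also named, was therefore used as the floor throughout. A probe set was tested if at least 2 of the 16 arrays exceeded the median of all values (292.74). The 67 control probe sets were left out, and 7824 probe sets were tested. The control probe sets were looked at apart from the tests, and 1 gene among them is not reported here. Of the tested values, 9.81% lay at the floor. Fold changes are those of fitted log2 means and can differ from ratios of mean intensities. Where arrays lay at the floor on the lower side of a comparison and none on the higher side, the fold change is a lower bound on this scale and is given as "at least". Where arrays of the higher side lay at the floor, the fitted value is no bound. No scaling was applied beyond the authors' own.

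Gene symbols came from the platform annotation table given with the values, which can be old. Among all probe sets, 10961 had 1 symbol, 546 had several and 1119 had none. Among tested probe sets these numbers were 6878, 385 and 561. No gene was named from a probe set with several symbols.

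A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). It left 8 residual degrees of freedom, and the prior added a median of 5.19. P-values were adjusted by the Benjamini-Hochberg method over all 7824 probe sets, and a probe set was called at an adjusted p under 0.05. All tests are two-sided. The main contrast was the mean of the 3 same-time differences between induced and control cells at 24, 48 and 72 h, with 6 arrays on each side. Other contrasts were the difference at each time, induced 12 h against control 0 h, each later control against control 0 h, and the differences between the 3 same-time effects (F test). With 2 arrays per group, their number limits the precision. No label says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

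Of 30 gene lists fixed before the data were examined, 29 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01. Each of 5606 genes entered with its probe set of highest mean. Camera compares a list with all other genes. The estimated correlation of camera, and fry, which asks whether a list moves 1 way on balance, were run beside it.

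Genes named in the text followed a rule fixed before the data were examined. It used probe sets with exactly 1 symbol and 1 probe set per gene, the one with the larger absolute test statistic. For the average effect it took the 15 largest rises and 15 largest falls among called probe sets whose effects at 24, 48 and 72 h shared a sign. For each other contrast it took up to 6 rises and 6 falls with all arrays of a group above all of the other group. For the difference between times it took the 6 smallest p-values. Members of a list may be named under it, and RUNX1T1 and RUNX1 always.

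The model was tested on simulated data for the real 7824 probe sets with 200 probe sets changed. For the average effect, 83.1% of 4-fold, 53.3% of 2-fold and 14.8% of 1.5-fold changes were recovered, with 4 false calls. Each of these changes was the same at 24, 48 and 72 h. The real data gave 0 calls at 24 h and 2499 in the average effect, so these shares need not hold there. For the 48 h effect, which stands for any same-time effect of 2 against 2 arrays, the shares were 68.5%, 14.7% and 5.08%. For 12 h against 0 h they were 68.4%, 24.2% and 5.17%. In a simulation with 1 list lowered by 0.5 on the log2 scale, camera called that list and 0 of the others. The simulated probe sets were drawn independently of each other, so this does not test false calls of lists whose genes are correlated.

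A position on the late effect was computed for each array over the 1219 probe sets called in the same direction at 48 and 72 h, with 0 for the mean of the same-time controls and 1 for the mean late effect. A first version had used the probe sets of the average effect, which includes the 24 h arrays themselves, and was replaced after its values had been seen. The alternatives tried were quantile normalization, median centring, other floors and filters, a pseudocount, no trend, array weights, a replicate term, the scale factor as a covariate, 1 probe set per gene, other baselines, fewer arrays in the fit, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.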

Results

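The series followed U937 cells over 72 h after induction of AML1-ETO, the fusion protein of t(8;21) acute myeloid leukaemia, beside uninduced control cells. It asks how gene expression in a myeloid cell line changes after the fusion gene is induced. Each of the 8 groups had 2 arrays. The median intensity of an array lay between 220.3 and 337.5, and 22.6% to 33.9% of the values of an array were below 0. Replicates of a group correlated at r = 0.912 to 0.955 across probe sets, and no pair held identical values. The first principal component held 43.1% of the variance and set the 4 induced arrays at 48 and 72 h apart from all others.

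RUNX1T1, the ETO part of the fusion, checked the labels. Of its 4 probe sets, the 1 that passed the filter read at most 91.4 in all 8 control arrays, which is under the floor of 135.61. It averaged 6312 ± 3306 (SD, n = 2) in induced cells at 48 h and 9479 ± 1590 (SD, n = 2) at 72 h. These levels were at least 43.2-fold (adjusted p = 0.000391) and at least 69.4-fold (adjusted p = 7.01e-05) above the controls of the same time. At 12 h both induced arrays lay under the floor. At 24 h, replicate 1 read 1592 and replicate 2 read -47.5, and the difference from the controls did not pass the test (log2 1.78 with replicate 2 set to the floor, adjusted p = 0.971). The other 3 RUNX1T1 probe sets read between -454.8 and 351.5 on all arrays. The 6 probe sets for RUNX1 also carry the names of 2 uncharacterised loci, so no RUNX1 level is given.

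**Figure D1:**
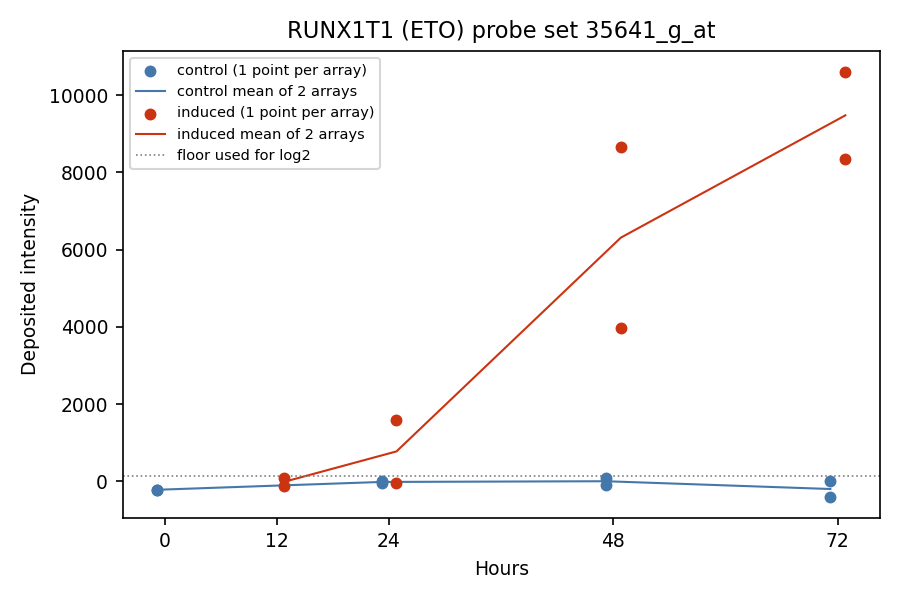
Deposited intensity (linear scale) of the tested RUNX1T1 probe set against hours, with 1 point per array, lines through the means of 2 arrays, and a dotted line at the floor of 135.61. Control arrays stay at or under 91.4, while induced arrays average 6312 at 48 h and 9479 at 72 h.

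Averaged over 24, 48 and 72 h, induced cells differed widely from controls. Apart from RUNX1T1, the largest fitted rise under the rule for named genes was that of EVI2B, a leukocyte membrane protein encoded within an intron of NF1 (at least 13.1-fold, log2 3.72, SE 0.23, adjusted p = 1.73e-07). ANXA1, which encodes the phospholipid-binding protein annexin A1, rose at least 11.6-fold (log2 3.54, SE 0.26, adjusted p = 5.18e-07). CD53, a tetraspanin of leukocytes, rose at least 11.5-fold, and PRAME, a tumour antigen, at least 8.30-fold. IRF9, a transcription factor of the interferon response, had a fitted log2 value of 3.11 (SE 0.43, adjusted p = 0.000106), which is no bound since 1 induced array of 24 h lay under the floor. The rule for named genes also took COL9A2, ECM1, SECISBP2L, CPN1, PPP2R5B, TMT1A, SEMA3A, ARID5B and H2BC21, with fitted log2 values of 2.47 or more and adjusted p-values of at most 0.00588.

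The largest fall was that of IRF8, a transcription factor of the monocyte lineage (log2 -3.70, SE 0.23, adjusted p = 1.80e-07). IRF8 averaged 113.8 ± 305.1 (SD, n = 2) in induced cells at 48 h against 6122 ± 554.1 (SD, n = 2) in controls. TUBA4A, an alpha tubulin, fell at least 9.19-fold and KCNAB2, a potassium channel subunit, at least 9.14-fold. SELPLG, the P-selectin ligand of leukocytes, fell at least 8.83-fold. DDIT4, an inhibitor of mTORC1 induced by stress, fell 7.96-fold, and the interleukin 17 receptor gene IL17RA at least 7.85-fold. The GTPase gene RAC2 of blood cells fell at least 7.57-fold, and MS4A3, a marker of granulocyte and monocyte progenitors, at least 6.35-fold. PLXND1, LST1, MFAP4, ZFP36L2, KRT9, ATP2A3 and MFNG completed the rule, all with log2 values of -2.50 or lower. The second called probe sets of TUBA4A, KCNAB2, RAC2 and ZFP36L2 moved the same way, at log2 -2.00, -1.35, -1.24 and -2.36.

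In all, 2499 of 7824 probe sets passed an adjusted p of 0.05, of which 1451 were higher and 1048 lower in induced cells. The share of higher calls was 58.1%, and became 50.9% after quantile normalization and 44.8% after median centring. The median log2 difference over all tested probe sets was 0.102. With control 0 h in place of the same-time controls, 1366 probe sets were called, and the calls of IRF9 (adjusted p = 0.0576) and ECM1 (adjusted p = 0.0783) ended.

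**Figure D2:**
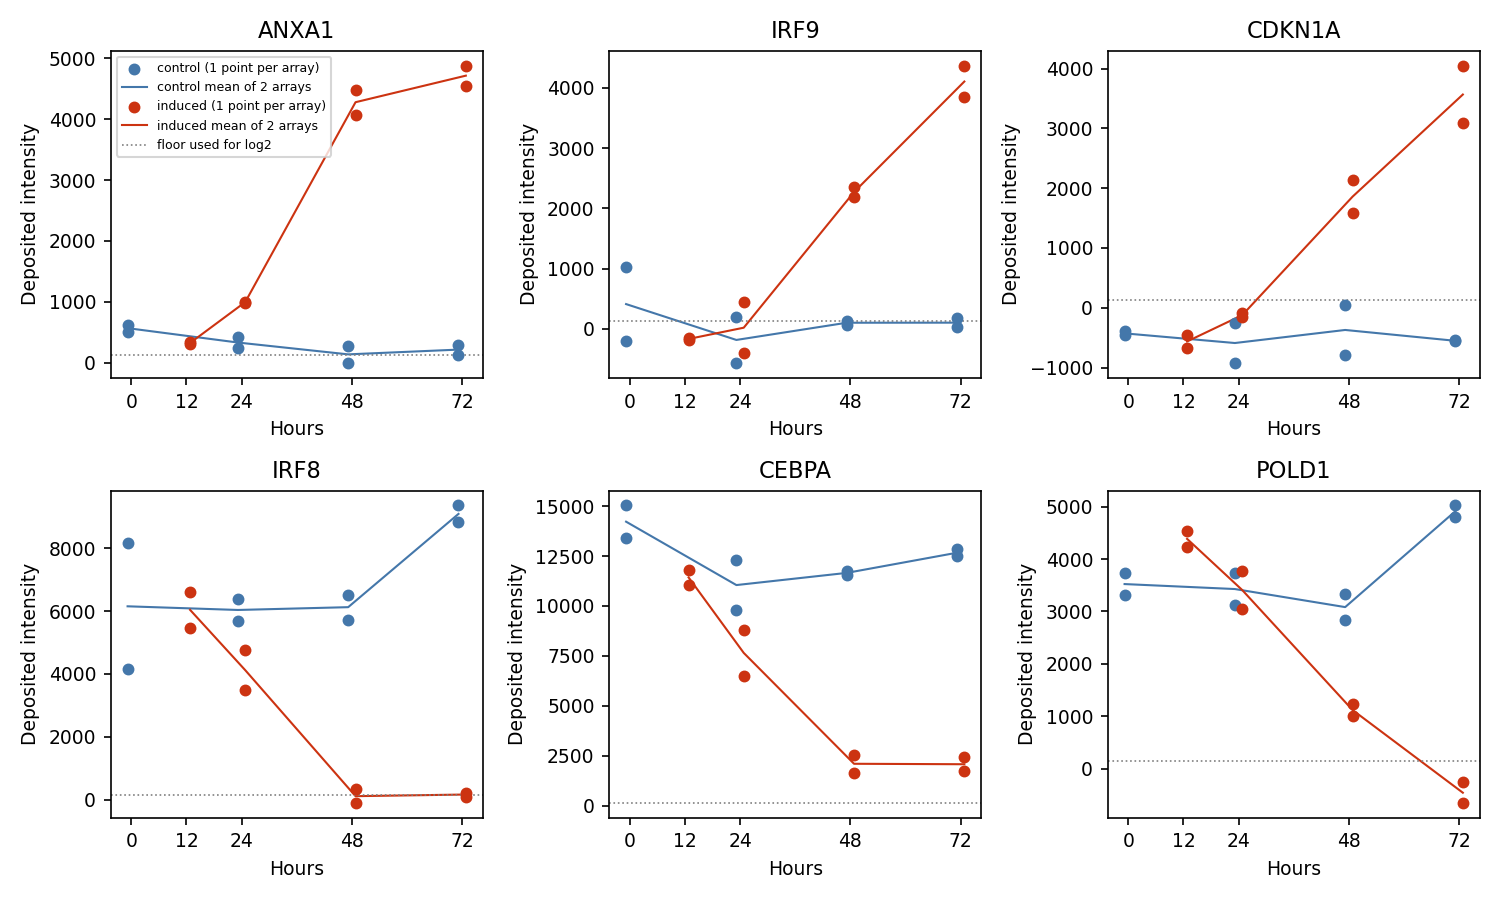
Deposited intensity (linear scale) of 6 genes against hours in control and induced cells, with 1 point per array, lines through the means of 2 arrays, and a dotted line at the floor of 135.61. ANXA1, IRF9 and CDKN1A are higher and IRF8, CEBPA and POLD1 lower in induced cells at 48 and 72 h; POLD1 averages 1119 at 48 h and lies under the floor at 72 h.

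Of 13 tested primary granule and promyelocyte genes, 8 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 1.97e-05, and 0.0174 with an estimated correlation). Cathepsin G (CTSG) fell 4.36-fold, proteinase 3 (PRTN3) 2.87-fold and the progenitor transcription factor MYB 2.13-fold. Among 15 granulocytic differentiation factors and late granule genes, 5 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.00491). That call was lost with an estimated correlation (adjusted p = 0.13). The transcription factor genes SPI1 (PU.1) and CEBPA fell at least 5.49-fold and 3.71-fold, and the integrin gene ITGB2 fell 2.83-fold. CSF3R, the receptor for G-CSF, rose 1.62-fold.

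Of 15 genes reported in other work as lowered by AML1-ETO, 7 were lower and 1 was higher, also when adjusted over the list alone (camera adjusted p = 0.00227, and adjusted p = 0.0724 with an estimated correlation). Of the 7, CTSG, AZU1, ELANE and RNASE2 are also in the granule list and CEBPA in the granulocytic list. Genes reported as raised went both ways. CDKN1A, the inhibitor of cyclin-dependent kinases p21, had a fitted log2 value of 2.82, with all control arrays and the 2 induced arrays of 24 h under the floor. JUP (plakoglobin) rose 4.57-fold, while MYC fell 4.24-fold and IGFBP7 2.17-fold. That list had 5 members higher and 4 lower of 15, also when adjusted over the list alone, and was not called (camera adjusted p = 0.972). Both lists came from studies of AML1-ETO in general, which may include this cell model, so they are not independent evidence of direction.

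In the list for DNA replication and S phase, 30 of 42 genes were lower and 1 was higher, with 33 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.29e-14, and 0.0174 with an estimated correlation). The polymerase gene POLD1 fell at least 4.65-fold, the helicase gene MCM4 3.49-fold and the licensing factor CDT1 2.66-fold. The higher member was CCNE2, a cyclin of the G1 to S transition (1.64-fold, adjusted p = 0.0477). Of 21 genes of MYC and ribosome biogenesis, 16 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 8.36e-10, and 0.00318 with an estimated correlation). RRS1 fell at least 3.97-fold, NOP2 2.71-fold and NOLC1 2.43-fold, while MXI1, which encodes an antagonist of MYC, rose 1.61-fold.

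Of 30 genes of the amino acid and unfolded protein responses, 22 fell and 1 rose, with 23 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.08e-12, and 0.0174 with an estimated correlation). The cystathionine lyase gene CTH fell at least 4.03-fold, the amino acid transporter gene SLC7A5 3.90-fold and AARS1, which charges tRNA with alanine, 2.84-fold. In the glycolysis and hypoxia list, 7 of 26 genes were lower and 4 higher, also when adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.104 with an estimated correlation). Its call also ended after quantile normalization and after median centring. Within it VEGFA fell 2.18-fold and HIF1A rose 2.41-fold. Of 45 cytosolic ribosomal protein genes, 0 passed the test singly, also when adjusted over the list alone. Their median of log2 -0.18 was called by camera (adjusted p = 0.000215), but not with an estimated correlation (adjusted p = 0.631).

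Of 11 replication-dependent histone genes, 8 were higher and 0 lower, and 10 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000852, and adjusted p = 0.0695 with an estimated correlation). The H2B genes H2BC14 and H2BC15 rose 3.69-fold and at least 3.65-fold. Of 30 interferon response genes, 17 rose and 2 fell, with 18 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.00227, and adjusted p = 0.312 with an estimated correlation). IFI16, a sensor of DNA, rose 4.93-fold and IFIT3 at least 3.78-fold, while IFITM3 fell 1.97-fold. With the stricter filter on low values the call of this list ended. Of 22 NF-kB and inflammatory genes, 10 rose and 3 fell, with 12 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.317 with an estimated correlation). The chemokine genes CXCL8 and CCL5 rose at least 4.11-fold and 2.92-fold.

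The other 18 lists were not called. Counts are those adjusted over all genes, with camera's adjusted p in brackets. In the apoptosis list, 6 genes were higher and 1 lower of 19 (0.131), with CASP8 2.35-fold higher and BID at least 4.51-fold lower. Of 12 p53 targets, 4 were higher and 1 lower (0.245), with CDKN1A and PMAIP1 up and TNFRSF10B down. Among 9 CBF cofactors and relatives, 2 were higher and 4 lower (0.217), and CBFB, the partner subunit of RUNX1, fell 1.57-fold. Among 17 monocyte and macrophage markers, 2 were higher and 4 lower (0.205). Among 35 mitosis and G2/M genes, 2 were higher and 7 lower (0.127). Of 23 adhesion and integrin genes, 10 were higher and 6 lower (0.544), with PECAM1 3.71-fold higher and CXCR4 3.85-fold lower. Of 12 Notch and Wnt genes, 4 were higher and 1 lower (0.0816). Of 12 stem and progenitor markers, 3 were higher and 0 lower (0.217), with LMO2 2.22-fold higher. Of 6 MHC class I genes, 3 were higher and 0 lower (0.148), and of 8 MHC class II genes, 1 was higher and 0 lower (0.98). Of 15 immediate early genes, 4 were higher and 3 lower (0.938). Of 49 oxidative phosphorylation genes, 5 were higher and 6 lower (0.217). Of 19 cholesterol synthesis genes, 2 were higher and 3 lower (0.689), and of 18 heat shock genes, 2 were higher and 3 lower (0.992). Among markers of other cell types, calls were 0 higher and 1 lower of 14 lymphoid markers (0.98), 0 and 1 of 12 erythroid and megakaryocyte markers (0.569), and 0 and 2 of 11 epithelial and fibroblast markers (0.349). Adjusted over the list alone, the counts became 3 higher and 6 lower for monocyte markers, 11 and 6 for adhesion genes, 7 and 1 for Notch and Wnt genes, and 0 and 0 for lymphoid markers, with no other change. Camera compares with other genes, whose values lay above 0 on balance, so for the raised AML1-ETO genes, immediate early, heat shock and lymphoid lists its direction was down although mean and median were above 0. For MHC class II genes the median was below 0 (-0.12) with the mean and the test above it, and for erythroid markers the median was above 0 (0.07) with the mean and the test below it.

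Camera thus called 11 of 29 lists, against 4 with an estimated correlation and 21 with fry. The number of called lists is no measure of the effect, since 17 of 100 splits of the 12 arrays within times, the real one included, gave as many. All 17 kept the real labels at 1 or more times and so may carry part of the effect. Drawn splits that kept them at no time gave up to 4 lists.

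**Figure D3:**
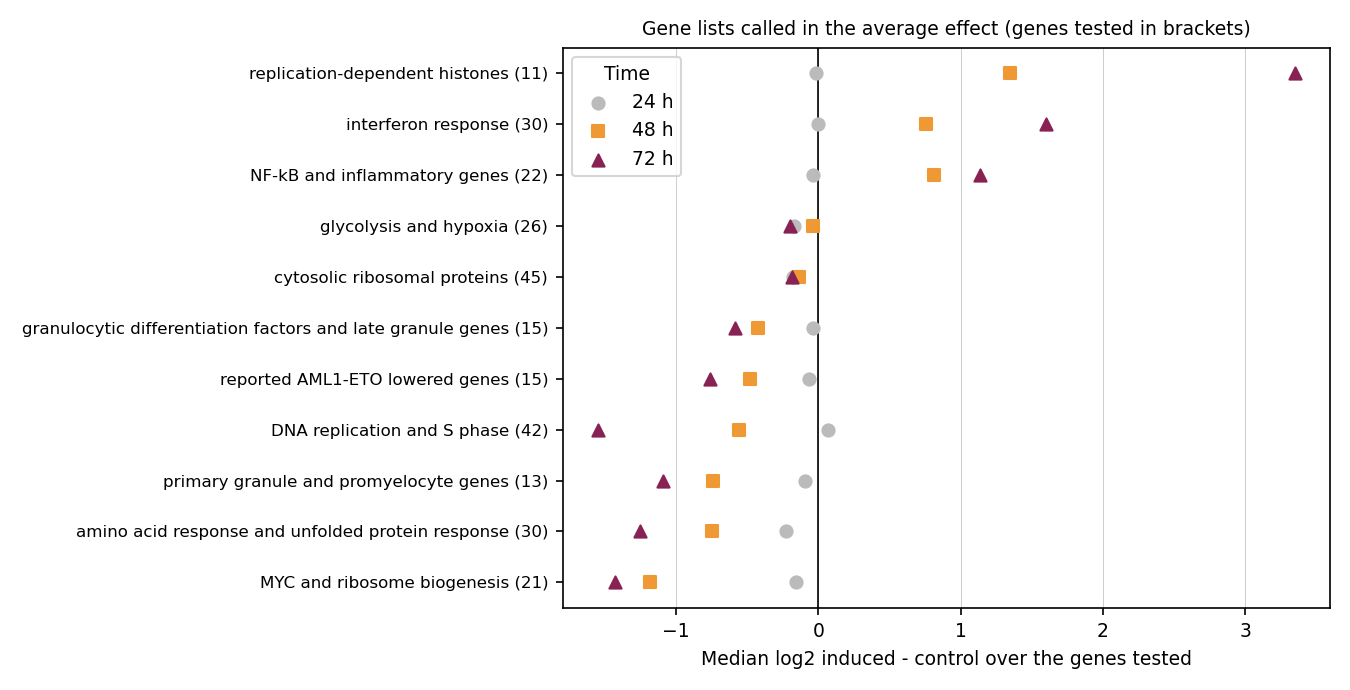
Median log2 difference between induced and control cells (horizontal axis) over the tested genes of each of the 11 lists called in the average effect, at 24, 48 and 72 h. The replication-dependent histones reach a median of 3.35 at 72 h, and the DNA replication list reaches -1.55.

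At 24 h no probe set passed the test with limma (0 of 7824; smallest adjusted p = 0.0515), and 397 had an unadjusted p under 0.05. Alternative settings gave between 0 and 4 calls. Camera called 7 of 29 lists at this time, and 0 with an estimated correlation. Those with a median above 0 were mitosis and G2/M (log2 0.34, adjusted p = 0.0838 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.797 with an estimated correlation). Those below 0 were the amino acid and unfolded protein responses, glycolysis and hypoxia, MYC and ribosome biogenesis, ribosomal proteins, and epithelial and fibroblast markers (adjusted p = 0.0838, 0.0741, 0.124, 0.795 and 0.0792 with an estimated correlation). In all 7 lists 0 genes passed the test singly, and adjusted over the list alone 1 did, in the amino acid list, where it was lower. Among the 1219 probe sets called in 1 direction at both 48 and 72 h, whose arrays are separate from those of 24 h, 72.9% had the same sign at 24 h. Their median difference in that direction was log2 0.15 at 24 h, against 1.36 at 48 h and 1.66 at 72 h. Of them, 121 had an unadjusted p under 0.05 at 24 h in that direction and 3 in the other. Beside this, EVI2B and CD53 differed by at least log2 1.87 each and SELPLG by log2 -1.94 at 24 h, without passing the test.

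At 48 h, 1499 probe sets were called, 820 higher and 679 lower. The largest fitted rises under the rule for named genes were those of RUNX1T1, EVI2B (at least 26.4-fold), ANXA1 (at least 21.8-fold), CD53, TMT1A and PRAME. IRF8 fell at least 28.9-fold (log2 -4.85, SE 0.39, adjusted p = 8.06e-06). CLUH, which encodes an RNA-binding protein of mitochondrial biogenesis, fell at least 21.8-fold, and KCNAB2, IL17RA, TRMT1 and LST1 each fell at least 16.6-fold. After median centring the share of higher calls was 43.8%, against 54.7% as deposited. Leaving out 1 of the 4 arrays of this time gave 854 to 933 calls.

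At 72 h, 2348 probe sets were called, 1258 higher and 1090 lower. The largest fitted rises under the rule for named genes were those of RUNX1T1, IRF9 (at least 26.2-fold), CDKN1A (at least 26.1-fold), H2BC21 (at least 24.8-fold), EVI2B and ANXA1. IRF8 fell at least 51.4-fold (log2 -5.68, SE 0.39, adjusted p = 4.93e-07), TUBA4A at least 41.4-fold and POLD1 at least 36.3-fold (log2 -5.18, SE 0.19, adjusted p = 4.37e-09). KCNAB2, RAC2 and MS4A3 followed, each at least 23.7-fold lower. Of 42 DNA replication genes, 35 fell and 0 rose, and of 35 mitosis and G2/M genes, 21 fell and 0 rose (camera adjusted p = 1.64e-20 and 1.73e-08, and 0.0102 and 0.0401 with an estimated correlation). Adjusted over the list alone, 35 and 22 fell and 0 rose. At 48 h, 6 genes of the mitosis list had been higher and 0 lower, and the list was not called (median log2 0.21, camera adjusted p = 0.241). Of 11 histone genes, 10 rose and 0 fell, with 10 and 1 when adjusted over the list alone (camera adjusted p = 1.58e-05, and 0.0225 with an estimated correlation). The median over all tested probe sets was log2 0.18, and median centring changed the share of higher calls from 53.6% to 43.2%.

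Between 48 and 72 h, 1225 probe sets were called at both times, and 1219 of these had the same sign. The 646 shared rises and 573 shared falls compare with 131.8 and 94.59 for independent lists. The effects correlated at r = 0.756 across probe sets, which are not independent replicates. The effect differed between 24, 48 and 72 h for 854 probe sets (F test). The signed log2 effect at 72 h lay above that at 24 h for 323 of these and below it for 531. Leaving out 1 array gave 463 to 815 calls. The 6 smallest p-values belonged to POLD1, TMC6, the transcription factor gene LYL1, KCNAB2, SLC7A5 and the mitochondrial chaperone gene TRAP1. All 6 were lower against controls at 72 h than at 24 h, so that their fall had grown. The log2 differences were -5.17, -3.69, -2.78, -4.38, -3.10 and -2.53, with F test adjusted p-values of at most 0.000115. The POLD1 effect, for example, was log2 -0.0112 at 24 h and -5.18 at 72 h. The values of POLD1 and KCNAB2 are bounds, since both lay under the floor in induced cells at 72 h.

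**Figure D4:**
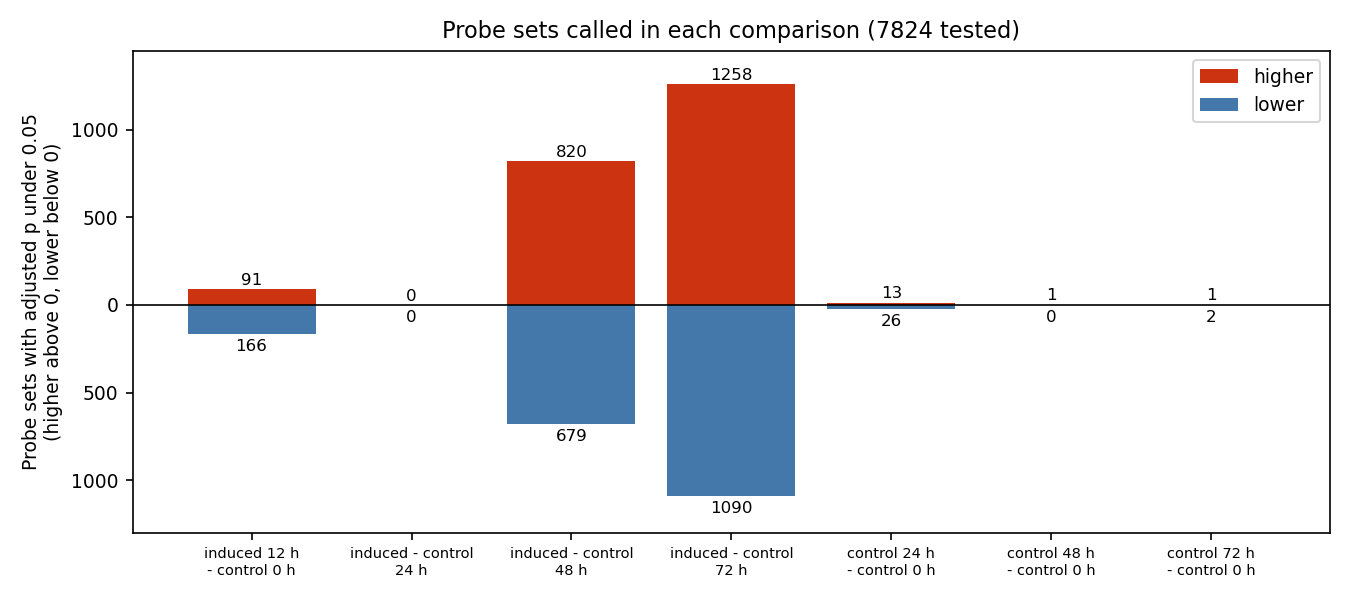
Number of probe sets with an adjusted p under 0.05 in each of 7 comparisons, out of 7824 tested, with those higher drawn above 0 and those lower below 0. Counts are 0 at 24 h, 1499 at 48 h and 2348 at 72 h, against 39, 1 and 3 for the controls of 24, 48 and 72 h compared with 0 h.

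Induced cells at 12 h had no control of that time and were compared with control cells at 0 h, so that induction and time in culture are mixed in this comparison. The nucleolar protein gene CCDC86 rose at least 18.5-fold (log2 4.21, SE 0.34, adjusted p = 8.04e-05), ARMC6 at least 13.3-fold and the ribosome assembly gene RRP12 at least 9.88-fold. ELAC2, which encodes a tRNA-processing enzyme, rose 7.88-fold, CAPN15 at least 8.11-fold and PEMT at least 7.59-fold. TSC22D3 (GILZ), a target of glucocorticoids, fell at least 12.0-fold (log2 -3.58, SE 0.45, adjusted p = 0.00186) and ALDH3B1 9.85-fold. The receptor gene P2RX7 fell, with a fitted log2 value of -2.77 (adjusted p = 0.014) and 1 of the 2 arrays of 12 h at the floor. The receptor genes CHRNB1 and AVPR1B and the centrosomal gene CEP57 fell between 5.89-fold and 6.35-fold. In all 257 probe sets were called, 91 higher and 166 lower. Leaving out 1 of the 4 arrays gave 80 to 150 calls, with 62 higher and 47 lower or 38 higher and 42 lower when it was a 0 h array.

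Of 21 genes of MYC and ribosome biogenesis, 4 were higher and 0 lower at 12 h than at 0 h (camera adjusted p = 2.94e-07, and 0.00752 with an estimated correlation), with 6 and 0 when adjusted over the list alone. Of 18 heat shock genes, 4 were higher and 0 lower (camera adjusted p = 6.26e-05, and 0.0177 with an estimated correlation), with 5 and 0 when adjusted over the list alone. Of 30 genes of the amino acid and unfolded protein responses, 9 were lower and 0 higher (camera adjusted p = 1.02e-05, and adjusted p = 0.196 with an estimated correlation), with 16 lower and 1 higher when adjusted over the list alone. Of 19 cholesterol synthesis genes, 3 were lower and 0 higher (camera adjusted p = 0.0246, and adjusted p = 0.559 with an estimated correlation), with 7 and 0 when adjusted over the list alone. The transferrin receptor gene TFRC rose by log2 2.02 (adjusted p = 0.00429).

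These calls depended on the baseline. Against control 24 h, 2 probe sets were called, both lower, and both were also lower against 0 h: CHRNB1 (log2 -2.31, adjusted p = 0.0472) and ATF5, a transcription factor of the amino acid response (log2 -1.40, adjusted p = 0.046). ATF5 was chosen after its values were seen, though it is a member of a list. CCDC86 then differed by log2 1.18 (adjusted p = 0.571) and TSC22D3 lay under the floor in both groups. With only the arrays of the contrast in the fit, 0 probe sets were called, and 1617 had an unadjusted p under 0.05 in the fit of all arrays. The share of higher calls was 35.4%, but 56.8% after quantile normalization and 73.4% after median centring, with a median over all probe sets of log2 -0.15 as deposited.

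Across the 7824 probe sets, the 12 h difference and the average later effect, which share no arrays, correlated negatively (r = -0.154, rho = -0.155; r = -0.205 to -0.0693 with 1 array left out). Of the 2499 probe sets called in the average effect, 35.5% had the same sign at 12 h. Signs were taken without centring, and the medians over all probe sets were log2 -0.153 at 12 h and 0.102 for the average effect. This offset can lower the share. CCDC86, for example, was higher at 12 h than at 0 h. At 48 h it was lower in induced cells than in controls and lay under the floor (log2 -2.47 or lower, adjusted p = 0.000228). But its controls also rose, from an average of -58.97 at 0 h to 1112 at 24 h and 753.6 at 48 h. Later controls are subtracted in the average effect, so a change of the cultures after 0 h can add to a negative correlation. The correlation therefore does not show that early and late effects of induction are opposite.

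Between 0 and 72 h, 3 probe sets were called in control cells, 1 higher and 2 lower, and 581 had an unadjusted p under 0.05. DDIT3 (CHOP), a transcription factor of the stress response, rose at least 5.77-fold on 1 of its 2 tested probe sets (adjusted p = 0.0179) and by log2 0.84 without passing the test on the other (adjusted p = 0.662). PRELP fell at least 12.6-fold and CYP2A13 at least 6.04-fold (adjusted p = 0.0179 each). Over all control times, 15 probe sets differed from 0 h (F test). Control 24 h against 0 h gave 39 calls, 13 higher and 26 lower, and control 48 h gave 1. No gene list was called by camera between 0 and 72 h (0 of 29, with 0 for an estimated correlation and 2 for fry). Each of the 3 gene calls ended when the fit held only the arrays of the contrast.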

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

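The count of kept calls for an aberrant 0 h array replaced a count of all calls, and the tests of RNA quality, of scaling, of induction alone, of an aberrant 0 h array and of a partial response at 24 h were chosen after the results they concern had been seen.

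The induction effect differed in size between 24, 48 and 72 h for 854 probe sets by the F test, and for 463 to 815 with 1 array left out. Among the 6 smallest p-values, the 72 h effect minus the 24 h effect was log2 -5.17 for POLD1, -3.69 for TMC6, -2.78 for LYL1, -4.38 for KCNAB2, -3.10 for SLC7A5 and -2.53 for TRAP1. Those of POLD1 and KCNAB2 are bounds set by the floor at 72 h.

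Control probe sets of the array took no part in the comparisons. In 4 of 252 combinations of a control probe set and an induced group, both arrays lay above all 8 control arrays and above the median of all values; chance alone would put both arrays above all 8 controls in 2.22% of combinations, or 5.60. At 12 h the TFRC probe sets averaged 2904 at the 3' end (highest control 1474) and 835.9 in the middle (highest control 407.7). Also at 12 h, the antisense ACTB probe sets averaged 3797 at the 3' end (highest control 1977) and 851 in the middle (highest control 694).

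The wide change in the average effect (2499 calls) was set against chance and 2 technical explanations. Of 100 splits of the 12 arrays within times, 2 gave as many calls, the real one included, which is under the bound set beforehand. The highest other count was 2612, from a split that kept the real labels at 2 of the 3 times. The 6 splits with the most calls, the real one among them, all kept the real labels at 2 or 3 times, and the highest count among the rest was 10. Such splits still carry much of the effect, which can raise the number of splits with as many calls. Drawn splits that kept the real labels at no time gave at most 1 call. These counts argue against a chance division of the 12 arrays as the source of the 2499 calls. The replicates may be technical, so the counts cannot speak to differences between cultures. For the 11 called lists chance cannot be excluded, since 17 of the splits gave as many, up to 13, nor for the 4 lists called with an estimated correlation (8 splits, up to 5). All of these splits kept the real labels at 1 or more times, so they are no clean measure of chance. Drawn splits that kept them at no time gave up to 4 lists by camera with the preset correlation. At most 1 of the 4 late induced arrays lay outside the range of all 8 controls for the 3' to 5' ratio of ACTB or GAPDH. That range includes the 0 h arrays, which are not in this contrast. The controls of 24 to 72 h had ACTB ratios of 1.19 to 1.38, and late induced arrays at 1.08, 1.04 and 1.09 lay lower. Their GAPDH ratios were 0.712 to 0.804, and late induced arrays at 0.702, 0.699 and 0.807 lay outside. The 0 h controls also lay below the controls of 24 to 72 h, at ACTB 0.931 and 1.18 and GAPDH 0.67 and 0.7. Yet they lay at 0.093 and 0.089 on the late effect, against 0.88 to 1.1 for late induced arrays. Replicate 2 of induced cells at 72 h, with ACTB 1.21 and GAPDH 0.807, lay at 1.1. These values argue against RNA quality, as far as these ratios measure it, as the cause of the late effect. Against a scaling offset, 2175 of the calls kept their sign and significance after median centring. The RUNX1T1 signal and the number of hours since induction rise together, so an effect of AML1-ETO and one of the inducing medium stay open, as no culture without the construct was analysed here.

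At 12 h against 0 h, 257 probe sets were called, and the comparison may mix induction with a change of the cultures after 0 h. When calls were made with 1 of the 0 h arrays and later controls were measured against the other, the uninduced controls of 24 to 72 h lay on the called side for 81.2% of 80 and 84.4% of 109 calls, which is consistent with 0 h cultures that differ from all later ones. Their median differences were log2 0.40 and 0.36, against 1.07 and 1.04 for the 12 h arrays. For a single aberrant 0 h array, at least 57 of the 257 calls kept their sign and significance with either array left out. Neither 0 h array alone therefore carried all of the calls. Most calls were not kept, and leaving out an array also lowers the precision. The count thus cannot tell whether 1 aberrant 0 h array lies behind the calls that were lost. Whether induction adds to a difference of the 0 h cultures cannot be told apart from time in culture. The calls lay a median of log2 0.38 (0.376) from control 24 h, against 1.20 from 0 h, and the same 12 h arrays enter both values.

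RUNX1T1 was above the floor on 1 of the 2 induced arrays at 24 h, with a share of 0.174 of its rise to 72 h in linear units on replicate 1 and of 0.00275 on replicate 2. Over 645 other probe sets that rose at 48 and 72 h, replicate 1 lay 0.0761 and replicate 2 lay 0.0641 of the way to 72 h. The difference of 0.012 is under the bound set for RNA of a later sample in replicate 1. But the controls spread from -0.0543 to 0.092 on the same measure, so a difference between 2 arrays cannot settle this. A partial response in both replicates stays open and cannot be told apart from the spread of the controls. The induced arrays of 24 h lay at 0.15 and 0.091 on the late effect, above the controls of 24 h (-0.033 and 0.034), but the lower of them lay -0.002 from the highest control, a 0 h array at 0.093. The bound for this test was changed after its value was seen: the first bound, all 8 controls, would have argued against a partial response, and the later one is the controls of 24 h.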

How the results depend on the processing

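The floor at the median, the pseudocount used here, the average over 48 and 72 h, the crossed replicate numbers and the 0 h swap were chosen after seeing the data. The planned floors at the 10th and 20th percentiles and the planned pseudocount were not run, since these percentiles are below 0.

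The average effect gave between 2109 and 2576 calls with each array left out in turn and 2924 over 48 and 72 h only. It moved beyond 1.5 times its count in 1 setting, with control 0 h as baseline (1366, a baseline that leaves out the controls' own change). The 72 h effect gave 1602 to 1873 calls with each array left out, and the average effect called 9 to 13 lists. Of 808 alternative values of the 30 genes named for the average effect, 806 kept their sign and significance, and the other 2 kept their sign. At 48 h, 191 of 191 values kept both, and at 72 h 202 of 202. At 12 h, 165 of 202 kept both and 37 lost significance, and for control 72 h these numbers were 27 and 17 of 44.

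The other counts moved as follows, and the cause was not tested unless stated. At 24 h, calls numbered 4 without a filter, 3 with the stricter filter, 2 without the trend, 1 with the scale factor as a covariate, 3 with 1 probe set per gene, and 0 to 1 with arrays left out. At 12 h they numbered 169 without a filter, 154 without the trend, 104 with array weights, 413 with the scale factor, 2 with control 24 h as baseline, and 0 with only the arrays of the contrast, which leaves 2 residual degrees of freedom. With arrays left out, which leaves a group with 1 array assumed to vary like the others, 12 h gave 80 to 150 calls and 48 h 854 to 933. The difference between times gave 463 to 815. The time effect in controls gave 24 calls with the floor at the median, 29 without a filter, 7 with array weights, 24 with the scale factor, 0 with only the arrays of the contrast, and 7 to 21 with arrays left out. The correlation of 12 h with later effects was -0.221 with the stricter filter, and -0.205 to -0.0693 with arrays left out.

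Called lists numbered 4 with an estimated correlation and 21 with fry for the average effect. At 12 h they numbered 2 and 8, with 3 to 7 when arrays were left out. For control 72 h they numbered 2 with fry, 2 with the scale factor, and 0 to 1 with arrays left out. Under fry, which does not compare with other genes, the direction turned up for the reported raised genes (median log2 0.0263) and the heat shock genes (median log2 0.107), whose medians did not change.

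Replicate numbers gave no clear pairing of the samples: over 28 pairs of groups, deviations of same-numbered arrays correlated at -0.15 to 0.25, and 7 pairs were over 0.1. Most of these correlations were positive, so an effect shared by same-numbered arrays is not excluded. A replicate block gave 2616 calls for the average effect, 0 at 24 h, 1564 at 48 h, 2425 at 72 h and 286 at 12 h. With the numbers of control 72 h crossed, the block gave 2357 calls at 72 h. Signal over background limits what can be seen: 37.6% to 44.5% of the values of an array lay at the floor, and changes between values at the floor have no size.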

Other observations

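The test below and the genes named from control 24 h were chosen after control values at 24 to 72 h of the genes called at 24 h had been seen.

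In uninduced cells 13 probe sets were higher and 26 lower at 24 h than at 0 h. TSC22D3, a target of glucocorticoids, fell to the floor (log2 -3.58 or lower, adjusted p = 0.00418), as did DDIT3, a gene of the stress response, on 1 of its 2 tested probe sets (log2 -2.45 or lower, adjusted p = 0.0143). BNIP3L, a mitophagy receptor induced by hypoxia, fell (log2 -1.86, adjusted p = 0.00564), and so did TXNIP, which binds thioredoxin and responds to glucose (log2 -1.20, adjusted p = 0.0291). The gene of the polyamine-degrading enzyme SAT1 fell on both its probe sets (log2 -1.69 and -1.36). CCDC86 rose by at least log2 3.03 (adjusted p = 0.00197), the proteasome subunit PSMD11 by 0.95 (adjusted p = 0.00838) and 1 of the 2 tested probe sets of the spermidine synthase gene SRM by 0.69 (adjusted p = 0.0291). At 72 h these values against 0 h were -0.12 for TSC22D3, -0.58 for BNIP3L, -0.25 for TXNIP, -0.23 and -0.20 for SAT1, at least 1.23 for CCDC86, 0.13 for PSMD11 and 0.20 for SRM. On its probe set named here DDIT3 had log2 0.84, which is no detected difference (adjusted p = 0.662).

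A hypothesis from this is that the start of the cultures, such as fresh medium, set off a response that faded by 72 h. It was tested over the 257 probe sets called at 12 h against 0 h, a choice that the controls of 24 to 72 h entered through the variance alone. In the called direction, controls lay a median of log2 0.75 from 0 h at 24 h, 0.54 at 48 h and 0.22 at 72 h. For 87.5% of the probe sets, control 72 h differed from control 24 h against the called direction, which includes any that passed beyond 0 h. A fading response would give such values, but no label records a change of medium, and the 0 h arrays enter all 3 medians. The same control arrays raised the hypothesis, so this is no independent test of it.

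The Alu control probe set read 2188 on replicate 2 of the induced cells at 48 h, and between 6684 and 20070 on the 8 control arrays.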
